A study of Homo sapiens with 3 samples.

How the data were processed

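RNA from 3 samples of HSC-4 cells was analysed: 2D culture with control siRNA, suspension culture with control siRNA and suspension culture with LATS2 siRNA, with 1 array per group. Per the labels, total RNA was isolated with a Promega ReliaPrep kit, and complementary RNA was amplified and labelled with Cy3 using Agilent's low-input kit. All 3 arrays lay on 1 slide, of Agilent design 072363. The duration of suspension, the siRNA sequences and the time after transfection are not given in the sources used here.

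The deposited scanner files hold, for each spot, an intensity that Agilent Feature Extraction had already background-subtracted and detrended, on a linear scale and without scaling between arrays, per the file headers. The file headers give Feature Extraction version 10.7.1.1, while the submitters' processing notes name version 9.5.1.1. Other deposited columns are flags per spot, per the file headers: well above background, saturated, and outlier. Probe positions in these files are on hg19. The deposited table of the whole series holds a linear intensity per probe that the authors normalized between arrays. Its ranks followed the scanner intensities (Spearman's rho of 0.9999988 or more on each array), its column median was 5.36 for each array, and its values had the pattern of quantile normalization. The software for that step is not given in the sources used here.

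Control spots and spots marked as outliers were left out (40, 55 and 63 non-control spots for 2D culture, suspension control and siLATS2), and no non-control spot was saturated. The processed intensity was put on the log2 scale and the array's 75th percentile of it was subtracted. Spots of 1 probe were averaged: 57901 of 58201 probes had 1 spot and 300 had 10. Names on the array were updated through a table of RefSeq genes for GRCh38.p14, used for names only. By accession 31104 probes matched, by symbol 3366 and by synonym 496, and 23235 kept the name on the array. A gene took the probe with the highest mean signal over the 3 arrays. A gene counted as measured in a comparison when that probe was well above background on both arrays, and 21702 names with a symbol entered. In suspension against 2D culture, 2074 genes were well above background on 1 of the arrays, and comparing the bright array with the floor of the other gave a bound of at least 2-fold for 202 higher and 357 lower genes, which are not in the counts. For siLATS2 against control the numbers were 901, 85 and 99.

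The arrays differ in brightness. The 75th percentile over all non-control spots, here with outlier spots kept, was 3.68 times as high in 2D culture as in the suspension control. For 22494 spots well above background on all arrays the median log2 difference before scaling was -1.68. The 7 bright spike-in probe sequences had a median difference of -0.24. Values compared between suspension and 2D culture are therefore relative to the bulk of transcripts on each array. Spot noise was taken from the probes with 10 spots. The pooled SD of log2 signal between spots was 0.37 below a log2 signal of 4, 0.09 from 6 to 8, and 0.05 above 12. This spread leaves out variation between cultures, labellings and arrays.

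With 1 array per group, no significance test was made. Genes were called at 2-fold. For 42 gene lists written before the data were examined, the median log2 difference of the measured members was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and a list stood apart below the 2.5th or above the 97.5th percentile (2000 random lists for each alternative). For siLATS2, lists were also set, after the data were seen, against 2000 random lists matched on the change in suspension in 200 bins. Lists with fewer than 3 measured genes were not described, and LATS2 was left out of the YAP/TAZ target list. Some genes are in more than 1 list. Named genes followed a rule also fixed beforehand: in each comparison the 10 largest rises and 10 largest falls whose detected probes all moved the same way and that also passed 2-fold with normexp and with quantile normalization (clone, accession and locus names excluded), a fixed set of Hippo pathway genes, up to 4 members of each list with the largest change, all measured YAP/TAZ target genes, and the 10 genes of each opposite overlap whose smaller change was largest. For the shared suspension control, unchanged arrays were simulated 1000 times.

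The 2-fold threshold and the list placement were tried on simulated values first. Simulated gene values did not pass through scaling, probe choice or the detection filter, so these steps were not tested. For suspension against 2D culture, with 12808 genes and spot noise alone, 4 of 12608 unchanged genes were called, as were 0 of 50 genes changed by 0.5 log2, 50 of 50 changed by 1.5, 49 of 50 changed by -1.5, and 50 of 50 changed by 3. For siLATS2 against control, with 12677 genes, 5 of 100 unchanged lists of 20 genes stood apart and 98 of 100 lists shifted by 0.5 log2 did.

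The alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median of detected probes, the mean of all probes of a gene, no filter on dim probes, only genes measured on all 3 arrays, outlier spots kept, the authors' normalized table, and scaling to the spike-in probes, which was added after the arrays' brightness was seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and R 4.3.3 with limma 3.58.1 for normexp. Exon and UTR annotation of the probes was not analysed here, and a few genes that the rule names are not reported here.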

Results

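Transcript levels were measured in HSC-4, an established line of human tongue squamous cell carcinoma, on Agilent single-colour arrays that carry 62976 spots. The first sample was grown as an adherent 2D culture after transfection with a control siRNA. The second received the same control siRNA and was kept in suspension, where cells are detached from a culture surface. The third was kept in suspension after transfection with an siRNA against LATS2, a kinase of the Hippo pathway that phosphorylates and restrains the transcriptional co-activators YAP and TAZ. Each condition was represented by 1 array, so no difference has a replicate check, no p-value is given, and the number of arrays limits the precision of every value. Signals well above background were recorded for 29069 of 60901 non-control spots in 2D culture (47.7%), for 23838 in the suspension control (39.1%) and for 24291 with siLATS2 (39.9%). The 75th percentile of the signal was 249.2 in 2D culture, 67.5 in the suspension control and 70.7 with siLATS2, and each array was scaled to this value. A gene is called higher or lower below when its normalized signal differed at least 2-fold, and differences are given on the log2 scale unless stated as folds.

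LATS2 mRNA, the target of the siRNA, was 3.83-fold lower in the siLATS2 sample than in the suspension control, a log2 difference of -1.94. Its normalized log2 signal was -0.33 in 2D culture, 0.08 in the suspension control and -1.86 with siLATS2. The gene is read by a single probe, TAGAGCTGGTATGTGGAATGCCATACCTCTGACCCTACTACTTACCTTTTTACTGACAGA, which the files place on chromosome 13 from 21547929 to 21547988 of hg19, on the minus strand, within transcript NM_014572. The spread between repeated spots of 1 array gives this difference an SD of 0.21, which covers spot noise but not differences between cultures. These signals were dim (71.2 and 19.5 before scaling), and the difference shrank to -0.79 with normexp background correction. LATS1, the related kinase, was well above background on the 2D array alone, so no fold is given for it.

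In suspension, against 2D culture, genes of the response to low oxygen were higher and genes of cell division and ribosome production were lower, as far as 1 array per condition shows. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 541-fold higher (9.08, spot SD 0.09), and CA9, the cell surface carbonic anhydrase IX, was 349-fold higher (8.45, spot SD 0.20). At the other end, FJX1 was 57.0-fold lower (-5.83), UHRF1, which helps to copy DNA methylation at replication, was 50.8-fold lower (-5.67), and RRM2, the small subunit of ribonucleotide reductase, was 32.1-fold lower (-5.01). Among 12808 genes measured on both arrays, 3118 were higher and 2682 lower, of which 990 and 1024 differed at least 4-fold. This comparison asks how loss of attachment alters expression in these cells.

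All 21 measured hypoxia response genes were higher in suspension, with a list median of 4.44, including NDRG1 (7.28), ANKRD37 (6.31) and LOX (5.38), the collagen crosslinking enzyme lysyl oxidase. Of 18 glycolysis genes, 13 were higher and 1 was lower, with ENO2, an enolase, at 7.37, HK2, a hexokinase, at 4.34, and PFKM, a phosphofructokinase, at -3.22. MB, which encodes the oxygen-binding protein myoglobin, was 6.41 higher and is in neither list. Stress genes were higher as well: of 20 genes of the unfolded protein response, 18 were higher, among them the endoplasmic reticulum chaperone HSPA5 (4.31), HERPUD1 (4.37) and DNAJB9 (4.22). Of 26 genes of the integrated stress response, 15 were higher and 3 lower, led by DDIT3 (6.04), VLDLR (5.33) and DDIT4 (5.15). FOS, a subunit of the AP-1 transcription factor, was 6.37 higher, and 13 of 17 measured AP-1 and immediate early genes were higher, against 2 that were lower. Of 23 autophagy and lysosome genes, 10 were higher and 1 lower, with the kinase ULK1 at 4.76.

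All 33 measured DNA replication and G1/S genes and all 38 mitosis and G2/M genes were lower in suspension, with medians of -3.53 and -3.12. They include DSCC1 (-5.22), CDC45, a part of the replicative helicase (-4.47), SPC25, a kinetochore protein (-5.28), and the mitotic kinases AURKB (-4.42) and CDK1 (-3.96). Of 26 ribosome biogenesis genes, 25 were lower, such as RRS1 (-5.28), NOP16 (-4.42) and DKC1 (-4.36), and 10 of 18 tRNA synthetase genes were lower, with FARSB at -4.09. METTL1, a tRNA methyltransferase, was lower too (-4.83). Of 14 heat shock genes, 10 were lower, including HSPE1 (-3.68) and HSPA8 (-3.62). Of 32 oxidative phosphorylation genes, 12 were lower and none was higher, with CYCS, cytochrome c, at -2.53. Of 13 fatty acid synthesis genes, 6 were lower and 3 higher, with ACACA (-2.97) and SCD (2.53) apart from each other. Of 11 histone genes, 8 were higher and 2 were lower, with H2AX at -3.89. H1-1, a linker histone gene outside that list, was 28.7-fold lower (-4.84); histone probes can share signal between close family members. Probes of 1 gene were uneven there: those of H2AC6 ran from 1.32 to 4.52 and those of H2BC21 from 0.30 to 4.05.

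Of 31 measured suprabasal keratinocyte differentiation genes, 23 were higher and none lower, including TGM1, the transglutaminase of the cornified envelope (4.31), RHCG (4.17) and KRT16 (3.55). Of 17 basal keratinocyte genes, 7 were higher and none lower, and that list did not stand apart from matched lists (median 0.31, percentile 59.1). Of 26 epithelial junction genes, 16 were higher and 1 was lower, with the desmosomal genes DSG3 (2.18) and PKP1 (2.07) among them. Of 17 TGF-beta response genes, 9 were higher and 3 lower, with TGFB1 at 3.28, CDKN2B at 3.26 and ID3 at -3.01. Of 16 matrix metalloproteinases and inhibitors, 7 were higher, with TIMP3 at 3.35 and MMP9 at 2.56.

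These 18 lists, 11 higher and 7 lower, stood outside the central 95% of 10000 random lists matched on mean signal, out of 40 lists described, where lists of randomly drawn genes would give 2. That figure treats genes as independent. Members of a list can vary together between cultures, so the figure does not measure variation between cultures. The calls ended without a filter on dim probes for the TGF-beta list (percentile 80.5) and the metalloproteinase list (96.6), and for the fatty acid list with normexp or with the mean of all probes. Scaling to spike-in RNA, an option added after the arrays' brightness was seen, moved the median of all genes by -1.69, left 463 genes higher and 8558 lower, and put 5.13% of called genes on the higher side against 53.8%. That split was 39.3% with normexp and 72.8% without the filter on dim probes. With spike-in scaling the medians of 7 of the 11 higher lists turned below 0: the integrated stress response (-0.16), suprabasal differentiation (-0.13), junction (-0.39), glycolysis (-0.38), TGF-beta (-0.61), metalloproteinase (-0.74) and autophagy (-0.88) lists. The hypoxia (2.75), unfolded protein response (0.51), histone (0.36) and AP-1 (0.25) lists stayed above 0. The list placements are therefore relative to other genes of similar signal.

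**Figure D1:**
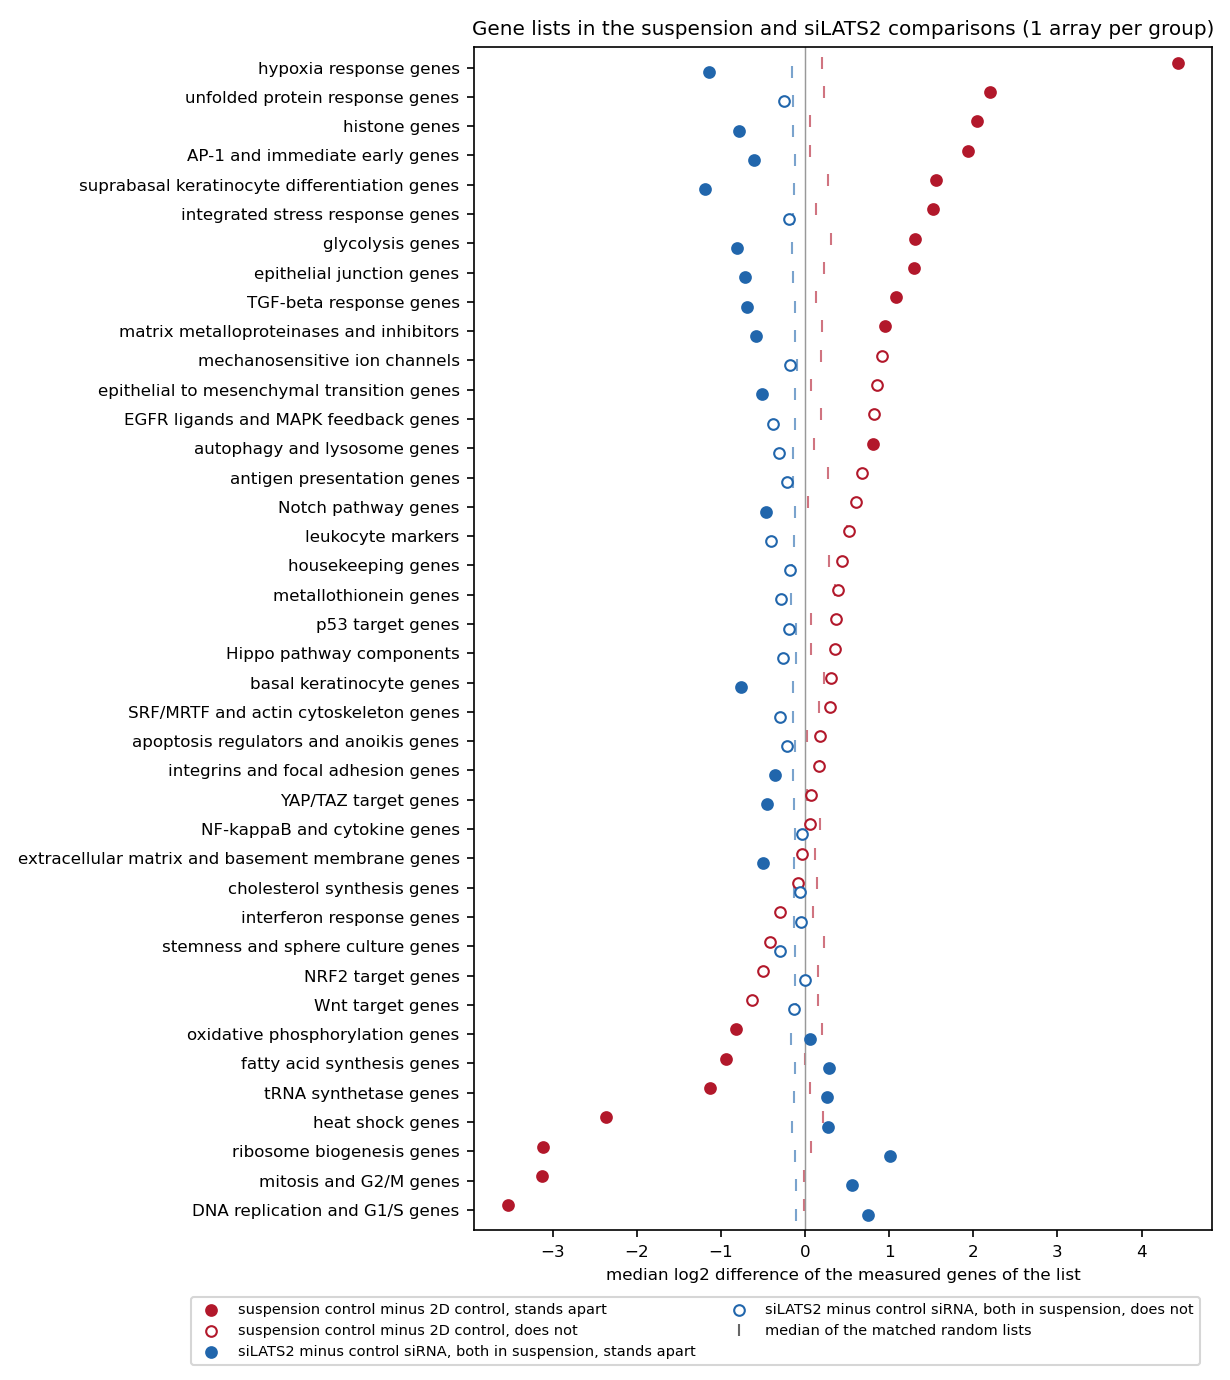
Median log2 difference of the measured genes of each of 40 lists, 1 row per list, for suspension control minus 2D control (red) and siLATS2 minus control siRNA in suspension (blue), from 1 array per group. Filled points stand outside the central 95% of matched random lists and vertical ticks mark the random median: hypoxia genes lie at 4.44 and -1.14 and DNA replication genes at -3.53 and 0.75, on 75th percentile scaling (7 of the filled red points above 0 turn below 0 with spike-in scaling).

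PIEZO1, a mechanically gated cation channel and the gene named in the series title, did not differ 2-fold between suspension and 2D culture on 75th percentile scaling. Its brighter probe, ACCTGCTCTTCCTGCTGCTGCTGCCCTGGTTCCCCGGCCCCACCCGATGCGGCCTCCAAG, lies on chromosome 16 from 88815792 to 88815851 of hg19, near the 5′ end of transcript NM_001142864, and gave 0.12 with a spot SD of 0.07. A second probe on the same chromosome, from 88782172 to 88782231, gave 0.41. Signals before scaling in 2D culture and the suspension control were 25870 and 7607 on the brighter probe, against 1177 and 422 on the second. The second probe lies nearer the 3′ end of the transcript, and why the probes differ so much in signal was not tested. The sign was not settled: the brighter probe gave -0.092 with quantile normalization, -0.082 in the authors' normalized table, -0.44 with normexp and -1.57 with spike-in scaling. Of the 14 measured mechanosensitive channels, 6 were higher, with TRPV4 at 3.23, and PKD2 was lower (-1.69). The list median of 0.91 lay at percentile 97.0, and the list stood apart under 3 of the 9 alternatives; it was -0.77 with spike-in scaling.

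The YAP/TAZ target genes went separate ways in suspension, relative to the bulk of transcripts on each array. CCN1, a matricellular protein gene widely used as a YAP readout, was 16.5-fold lower (-4.05) on a probe that lies on chromosome 1 from 86048953 to 86049012 of hg19, and FJX1 (-5.83) and NT5E (-1.66) were also lower. IGFBP3, an insulin-like growth factor binding protein, was 65.1-fold higher (6.02), and GADD45B (3.66) and F3 (1.24) were higher, F3 turning to -0.44 with spike-in scaling. The other 9 of the 15 measured targets differed less than 2-fold, and the list median of 0.07 lay at percentile 53.1 of matched lists. Spike-in scaling moved the median of all genes by -1.69, more than 2-fold, and gave a list median of -1.62. The calls of less than 2-fold for these targets, and for YAP1 and WWTR1 below, therefore depend on the scaling. CCN2 was well above background in 2D culture alone and ANKRD1 on no array, so neither has a fold. YAP1 (0.63) and WWTR1, which encodes TAZ (-0.07), differed less than 2-fold, while among Hippo pathway components TEAD3 was higher (1.87) and NF2 (-2.68) and TEAD4 (-2.12) were lower.

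**Figure D2:**
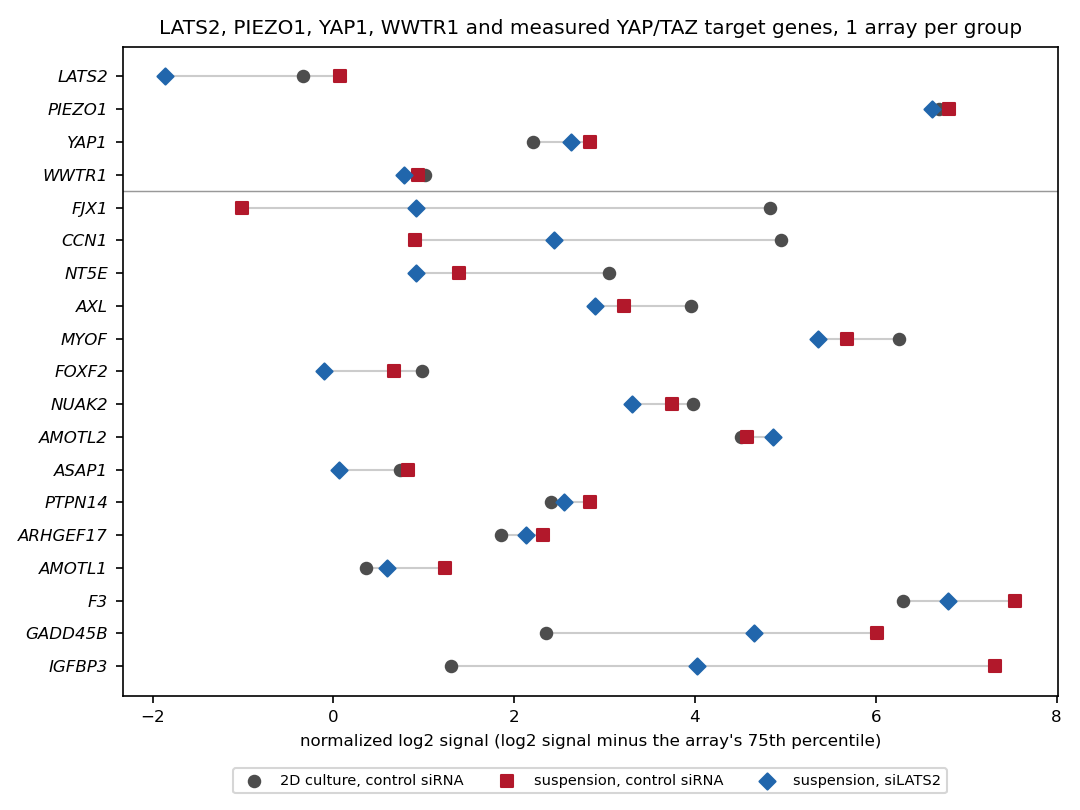
Normalized log2 signal (log2 signal minus the array's 75th percentile) of LATS2, PIEZO1, YAP1, WWTR1 and the 15 measured YAP/TAZ target genes, with 1 point per array for 2D control (grey circles), suspension control (red squares) and suspension siLATS2 (blue diamonds). Grey lines span the 3 values: LATS2 is lowest with siLATS2 at -1.86, PIEZO1 stays between 6.62 and 6.82 on its brighter probe, and CCN1 goes from 4.95 in 2D culture to 0.90 in suspension and 2.44 with siLATS2.

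With siLATS2 in suspension, against the control siRNA in suspension, keratinocyte differentiation and hypoxia genes were lower and ribosome biogenesis genes were higher. Beside genes with a like change in suspension, the suprabasal differentiation list still stood lower (-1.19 against -0.48). The hypoxia (-1.12 against -1.03) and ribosome biogenesis (1.01 against 0.86) lists did not stand apart from such genes. IGFBP3 was 9.87-fold lower (-3.30, spot SD 0.02), and the matrix metalloproteinase genes MMP9 (-2.67) and MMP1 (-2.45) and the collagen crosslinking enzyme gene LOX (-2.45) were each at least 5-fold lower. HSPA6, a stress-inducible member of the HSP70 family, was 8.70-fold higher (3.12, spot SD 0.21) on a probe that can share signal with related genes, and the chemokine gene CCL5 was 5.03-fold higher (2.33). Among 12677 measured genes, 387 were higher and 676 lower, and 8 and 42 of them differed at least 4-fold. This comparison asks what silencing of LATS2 alters in cells without attachment.

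Other genes with the largest rises were TMEM177 (2.43), MYL9, a myosin light chain gene (2.29), TSPAN4 (2.18), the interferon lambda gene IFNL1 (2.12) and TMEM109 (2.05). Further large falls were those of ETAA1, a gene of the replication stress response (-3.18), EDN2, which encodes endothelin 2 (-2.79), and COX4I1 (-2.57). The other 31 genes of the oxidative phosphorylation list, which holds 32 measured genes including COX4I1, differed less than 2-fold, and the list median was 0.06. Each of ETAA1, EDN2 and COX4I1 was read by 1 spot.

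Of 27 measured suprabasal differentiation genes, 17 were lower with siLATS2 and none was higher, with KRT16 (-2.08), SBSN (-1.91), KRT6B (-1.76) and RHCG (-1.70) at the front; the keratin probes can share signal between close family members. Of 17 basal keratinocyte genes, 6 were lower, among them SOX2 (-1.28) and KRT15 (-1.27), and of 25 junction genes 6 were lower, including the gap junction gene GJB2 (-2.03) and DSG3 (-1.87). Of 22 hypoxia response genes, 13 were lower and none higher, with CA9 at -2.10 and ANGPTL4 at -1.85. The glycolysis genes ENO2 (-1.54) and GAPDH (-1.15) were lower, as were 4 of 18 in that list. Of 17 TGF-beta response genes 3 were lower, among them TGFB1 (-1.92) and INHBA (-1.40), and 5 of 14 metalloproteinases and inhibitors were lower. AP-1 genes followed with 3 of 19 lower, EGR2 (-1.80), FOS (-1.36) and JUN (-1.16). In the histone, epithelial to mesenchymal transition and Notch lists 2 of 11, 2 of 10 and 2 of 14 genes were lower and none higher, and in the extracellular matrix list 4 of 23 were lower and 1 higher. In the integrin list 1 of 24 was lower, a share no larger than among all genes (5.33%), and the list median was -0.36 against -0.14 in matched random lists.

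Of 26 ribosome biogenesis genes, 14 were higher with siLATS2 and none lower, including POLR1B (1.48), LYAR (1.45) and RRS1 (1.45), and the list median was 1.01 (0.61 with normexp). DNA replication genes lay above 0 in 31 of 33 cases, and 9 passed 2-fold, among them UHRF1 (1.67), E2F1 (1.51) and CDC45 (1.32). Mitosis genes lay above 0 in 34 of 38 cases, and 4 passed 2-fold, among them AURKB (1.55), MAD2L1 (1.12) and CDK1 (1.09). Among tRNA synthetase genes 3 of 18 were higher, with LARS1 at 1.60. The heat shock, fatty acid synthesis and oxidative phosphorylation lists had medians of 0.27, 0.28 and 0.06 against -0.15, -0.12 and -0.16 in matched random lists.

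In all, 7 lists stood above and 14 below matched random lists, out of 40, where lists of randomly drawn genes would give 2. The suspension control is shared with the other comparison. Beside random lists matched on their change in suspension, a check added after the data were seen, none of the 7 stood above. DNA replication (percentile 2.10) and mitosis (0.05) stood below, and so did 8 of the 14, with the integrin list (2.35) near the limit. The median of all genes was -0.12, it moved by 0.14 with quantile normalization and with the authors' normalized table, and the share of called genes that were higher was 36.4%, against 54.0% and 54.3% under those settings and 16.6% with normexp. The medians of the 21 lists kept their sign under all 9 alternatives. The call ended for the integrin list with normexp (percentile 5), without the filter on dim probes (2.70) and with outlier spots kept (2.65), and for the Notch list without that filter (5.70).

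YAP/TAZ target genes were not raised as a list by siLATS2. CCN1 (1.54, spot SD 0.12) and FJX1 (1.93) were higher, IGFBP3 (-3.30) and GADD45B (-1.37) were lower, and the other 11 differed less than 2-fold, from -0.77 for ASAP1 to 0.29 for AMOTL2. The 200 genes nearest in their change in suspension moved the same way, with medians of 1.07 for CCN1, 1.08 for FJX1, -1.01 for IGFBP3 and -0.88 for GADD45B. Among these neighbours, 23 rose more than CCN1 and 4 more than FJX1, while 41 fell further than GADD45B and 0 further than IGFBP3. FJX1 and IGFBP3 lay near the ends of the range in suspension, so their neighbours mostly changed less there. Standing beyond the neighbours is therefore partly built in for FJX1 and IGFBP3. The list median of -0.45 lay at percentile 1.28 of matched lists, and 3 of 15 genes lay above 0; it no longer stood apart with normexp, with quantile normalization or without the filter on dim probes. PIEZO1 was -0.20 on its brighter probe and -0.26 on the other, and the brighter probe gave 0.092 with quantile normalization and 0.084 in the authors' normalized table. YAP1 (-0.21) and WWTR1 (-0.15) differed less than 2-fold.

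Genes that were higher in suspension tended to be lower with siLATS2, and the reverse. Of the 385 genes higher with siLATS2 and measured on all 3 arrays, 330 were lower in suspension, and of the 656 lower with siLATS2, 481 were higher in suspension. TMEM177 (-5.18 in suspension, 2.43 with siLATS2), FJX1 (-5.83, 1.93), TSPAN4 (-3.52, 2.18), WDR43 (-4.19, 1.95) and the DNA polymerase theta gene POLQ (-4.07, 1.83) show the first direction. IGFBP3 (6.02, -3.30), MMP9 (2.56, -2.67), LOX (5.38, -2.45), PCSK5 (4.65, -2.42) and CALHM3 (3.80, -2.54) show the second. The HSPA6 and CCL5 genes were among 11 that were higher in both comparisons, and 8 were lower in both.

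Across the 12583 genes measured on all 3 arrays, Pearson's r between the 2 comparisons was -0.65 and Spearman's rho -0.62; genes are not independent replicates. The suspension control enters both comparisons with opposite sign, which by itself gives r = -0.58 in simulated unchanged arrays with spot noise alone. It gives r = -0.50 when the spread between the suspension arrays, as a median absolute deviation, is taken as noise split equally over the arrays. Noise gives an r of about this size whatever its amount, so these r values do not measure an excess. In the second kind of simulation the covariance was -0.12, against -0.54 observed, a difference of -0.42. The overlaps simulated in that way averaged 43.8 and 44.5 genes (at most 67 and 66), and independent lists of these sizes would share 81.8 and 156.5. The simulated arrays held no change in suspension, so few of their genes passed 2-fold and small overlaps were fixed by the setting. They are no reference for the observed overlaps. A control noisier than the other arrays would also make the covariance difference smaller. The control is a single array and cannot be split, so part of the excess may come from it. Against 2D culture, the interquartile range of log2 differences was 1.76 for the suspension control and 1.44 for siLATS2.

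**Figure D3:**
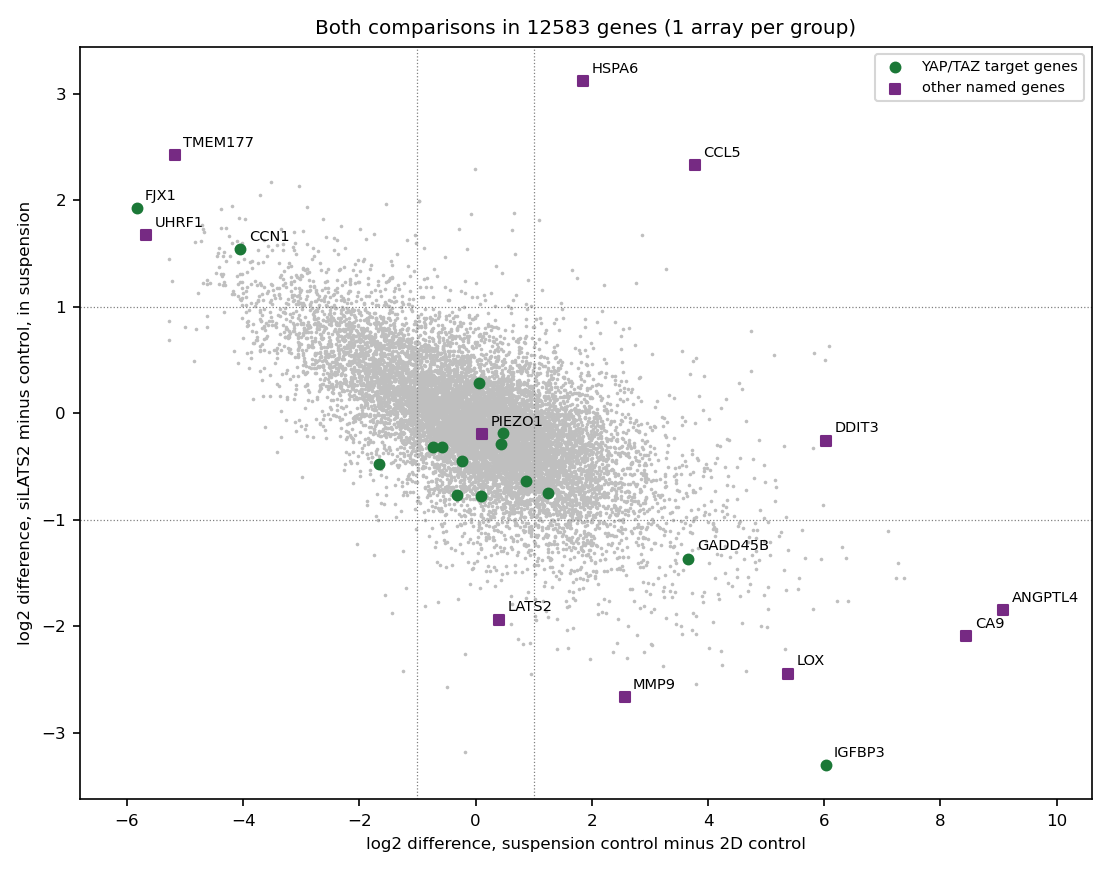
Log2 difference of siLATS2 minus control in suspension (vertical) against suspension control minus 2D control (horizontal) for 12583 genes, 1 grey point per gene, from 1 array per group; dotted lines mark 2-fold. YAP/TAZ target genes are green circles and other named genes purple squares: FJX1 (-5.83, 1.93) and IGFBP3 (6.02, -3.30) lie at opposite corners, and HSPA6 and CCL5 are higher in both.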

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

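The spike-in scaling was chosen after the data were seen, and the other alternatives before the data were examined. No paired analysis was possible because each group has 1 array, and the slide as a block was not run because all arrays lay on 1 slide. LATS2 stayed lower with siLATS2 under all 9 alternatives (from -2.04 to -0.79). It is read by 1 probe that was well above background on all arrays. The mean of all probes and the changed filters therefore could not alter its value (-1.94). Normexp, which treats background differently, gave -0.79, less than 2-fold. The lists that stood apart did so under all 9 in 15 of 18 cases in suspension and in 18 of 21 with siLATS2. Spike-in scaling and centring subtract 1 value per array from all genes, so they could change a call only through new random lists. The authors' table has the pattern of quantile normalization, so it is close to that setting and adds little to it. Signal over background limits dim genes: CCN2 and LATS1 were not well above background in suspension, and LATS2 with siLATS2 (-1.86) lay near the lowest detected level of its array (-2.73).

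With normexp, LATS2 was -0.79 with siLATS2, PIEZO1 -0.44 in suspension, the YAP/TAZ list median -0.43 in suspension and -0.29 with siLATS2, and r -0.61. That setting gave 1985 genes higher in suspension, 62 higher and 312 lower with siLATS2, and overlaps of 53 (lower, then higher) and 211 (higher, then lower); its offset of 50 shrinks differences of dim genes by construction. Without the filter on dim probes 21702 genes entered, with 9301 higher and 3469 lower in suspension, and 1104 higher and 1481 lower with siLATS2. The overlaps were then 667 and 1119, and r was -0.52. The median of all genes in suspension was 0.69, against 0.14 with the filter. After scaling, the lowest detected level was -4.49 in 2D culture and -2.55 in the suspension control. Scaling thus places signals near background higher on the suspension array, and the count of higher genes without the filter includes this. Unchanged arrays, simulated with the filter, gave r from -0.58 to -0.50. Noise alone gives an r of that size whatever its amount, and no covariance is given for this setting, so these r values decide nothing here. Quantile normalization gave PIEZO1 -0.092 in suspension and 0.092 with siLATS2, a YAP/TAZ median of -0.25 with siLATS2 and 317 genes higher in suspension and lower with siLATS2. In the authors' normalized table PIEZO1 was -0.082 and 0.084, the YAP/TAZ median with siLATS2 was -0.25, 613 genes were higher with siLATS2 and 513 were lower in suspension and higher with siLATS2. Centring on detected probes put PIEZO1 at 0.22 in suspension, and the mean of all probes put it at 0.26 with r at -0.64. For these settings the cause was not tested further.

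Spike-in scaling, which shifts all genes alike, gave 463 genes higher and 8558 lower in suspension, 196 higher in suspension and lower with siLATS2, PIEZO1 at -1.57 and the YAP/TAZ median at -1.62. The shift was -1.69 in suspension, so every gene that rose by less turned below 0. Among them were F3 (-0.44), HLA-F (-0.037), IFITM1 (-0.056), KRT17 (-0.0099), POU5F1 (-0.54), PTPRC (-0.058) and TGFB1I1 (-0.30). MYC in suspension turned to 0.35 with the mean of all probes, and the cause was not tested. The TGF-beta list median, relative to all genes, turned to -0.28 without the filter on dim probes. The median of all genes moved by 0.55 in that setting.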

Other observations

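The tests on brightness and on mixed RNA, and the comparisons with genes matched on their change in suspension and with noncoding transcripts, were chosen after the results were seen. Against 2D culture, the siLATS2 sample, like the suspension control, differed widely: 2148 genes were higher and 2620 lower among 13095 measured. All 39 DNA replication genes and all 39 mitosis genes were lower (medians -2.82 and -2.63), and 20 of 21 hypoxia response genes were higher (median 3.47). For the unfolded protein response the list median was 2.20 for the suspension control and 1.96 for siLATS2 against 2D culture, and the direct difference of -0.25 lay at percentile 17.4 of signal-matched lists. DDIT3 was 6.04 higher in suspension and HSPA5 4.31, and the integrated stress response list differed by -0.19 with siLATS2 (percentile 32.8).

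Beside genes with a like change in suspension, 11 of 40 lists stood apart with siLATS2, 10 lower and 1 higher, where lists of randomly drawn genes would give 2. Suprabasal (-1.19 against -0.48 in matched lists), basal keratinocyte (-0.76 against -0.22), junction (-0.71 against -0.33), TGF-beta (-0.69 against -0.25), glycolysis (-0.80 against -0.45), extracellular matrix (-0.49 against -0.12), integrin (-0.36 against -0.16) and YAP/TAZ target (-0.45 against -0.08) lists were lower than such genes. DNA replication (0.75 against 0.93) and mitosis lists (0.56 against 0.80) were also below them, and the unfolded protein response list was above (-0.25 against -0.56). Of the lists that stood lower among signal-matched lists, hypoxia (-1.12 against -1.03), AP-1, histone, metalloproteinase, epithelial to mesenchymal transition and Notch were not set apart here. Of those that stood higher, ribosome biogenesis (1.01 against 0.86), tRNA synthetase, heat shock, fatty acid and oxidative phosphorylation were not.

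Among housekeeping genes, GAPDH was 1.90 in suspension and -1.15 with siLATS2, while the list medians (0.44 and -0.17) did not stand apart. Of 33 interferon response genes 1 was higher with siLATS2, OASL (1.13), and the list lay at percentile 82.0. The apoptosis, p53 target, NRF2 target, Wnt target, stemness, cholesterol, antigen presentation, metallothionein, NF-kappaB and SRF lists stood apart in neither comparison on 75th percentile scaling. A call appeared under 1 of 9 alternatives for the apoptosis list (mean of all probes, higher in suspension at percentile 98.2 and lower with siLATS2 at percentile 1), the NRF2 list (no filter on dim probes, lower in suspension at 1.95) and the NF-kappaB list (quantile normalization, higher with siLATS2 at 97.55). BBC3 (2.48) and BMF (2.44), which promote cell death, were higher in suspension. The list of EGFR ligands and MAPK feedback genes lay near the limits, with a median of 0.82 in suspension (percentile 96.7, and -0.87 with spike-in scaling) and -0.38 with siLATS2 (percentile 2.54), and it stood apart under 3 of 9 alternatives in suspension (higher) and under 6 of 9 with siLATS2 (lower). Of markers of other cell types, 2 fibroblast and 1 endothelial genes were measured, and the leukocyte list (5 genes) had a median of 0.53 in suspension at percentile 51.7, with PTPRC at 1.63 (-0.058 with spike-in scaling). Long noncoding RNAs were shifted upward in suspension: the median of 856 was 0.83, against 0.35 for protein-coding genes of like signal (at most 0.50 in 1000 draws), and with siLATS2 the 850 measured lay at -0.11 against -0.12. With spike-in scaling the suspension medians were -0.85 and -1.34, below 0 for both kinds.

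The arrays of suspended cells were dimmer for cellular transcripts. If less labelled material had been hybridised, the spike-in RNA would have dimmed as much, but the spike-in difference lay 1.44 log2 above the cellular one. That argues against hybridisation as the source. A smaller amount of cellular RNA in the labelling reaction, or a smaller share of messenger RNA within total RNA, may remain as explanations, and the design cannot separate them, because the amounts used are not given in the sources used here.

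The wide spread of changes in suspension was set against 3 technical explanations. Shorter RNA fragments would lower probes far from the 3′ end. The 5′ probe minus the 3′ probe of 1578 transcripts differed by 0.042 (95% interval 0.02 to 0.07), which goes against this. With 1 array per group, that interval reflects spread across transcripts and not variation between cultures or arrays. GC content of the probe had a Spearman's rho of 0.089 with the change over 16952 probes, too small to account for the spread. Noise of dim spots would narrow the spread among bright genes, but their interquartile range was 0.97 of that over all genes. A biological effect of suspension may remain, as a hypothesis, as may a difference between single cultures in density, medium or handling.

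The opposite changes in the 2 comparisons may come from the shared control. Spot and probe noise was tested by taking separate probes of the same gene for each comparison. With separate probes, r stayed at -0.53 over 3145 genes (95% interval -0.56 to -0.49). The 95% intervals in this paragraph reflect spread across genes, which are not independent replicates. They leave out variation between cultures and arrays. RNA of the 2D culture mixed into the siLATS2 sample would need 1 share for all genes, but genes at least 4-fold higher in suspension needed a share of 0.46 and genes at least 4-fold lower needed 0.10, a difference of 0.35 (95% interval 0.33 to 0.37, and 0.26 to 0.44 over 4 other settings). An effect of the LATS2 siRNA stays open, whether through LATS2 or not. So does a suspension control culture that had gone further into low oxygen and growth arrest than the siLATS2 culture for reasons unrelated to LATS2. With 1 culture of each, these cannot be separated.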
